A study of Mus musculus with 2 samples.

How the data were processed

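Total RNA was sequenced from the mouse MEL cell line, an immortalised erythroleukemia line, as 2 libraries that the labels name biological replicates 1 and 2 of a single group. Both labels cite the same biosample record, and nothing in the labels says whether the libraries came from separate cultures. Differences between the libraries therefore measure the spread between these samples, which may be technical. With 1 group there was no contrast between conditions, and the analysis describes levels, gene groups, isoforms and the differences between the replicates.

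Per the file headers and the file lists beside them, the authors deposited 1 gene table and 1 transcript table per library, made from a transcriptome alignment to mm10 with the GENCODE M4 annotation. The column names are those that RSEM writes. The quantification tool, its version and the aligner were not given in the sources used here. The deposited expected counts are estimated fragment numbers that need not be whole, with no normalization. The deposited TPM values are counts over effective length, scaled by the authors to the same total over all features in each library, and the deposited FPKM values are proportional to them. The deposited posterior mean counts and posterior mean TPM are a second estimate of the same quantities. In the deposited transcript tables, the percent of a gene's abundance held by each transcript is given. The lists of files beside the tables name separate signal tracks for the plus and minus strands, but whether the counting used strand is not stated.

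The tables held 69691 features, of which 43346 were Ensembl genes, 26248 had numeric identifiers and 97 were spike-in sequences. Gene symbols, biotypes and coordinates (GRCm38, the mm10 assembly) came from GENCODE M21, matched by identifier without version for 42462 genes (98.0%). The other 884 genes have no symbol here and entered no list. Library totals were 39453599 expected counts in replicate 1 and 56660375 in replicate 2. A floor of 3 counts corresponded to 0.0510 TPM in replicate 1 and 0.0300 TPM in replicate 2 for a gene of 1000 bases. Counting limits cover counting error only, since fragments without molecular identifiers are not independent molecules. Features shorter than 300 bases held 1.72% ± 0.291 (SD, n = 2) of the counts but 32.7% ± 4.94 of TPM, because the effective length of such features is small. TPM of short RNAs is therefore uncertain, and it lowers the TPM of all longer genes in a library.

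A protein-coding gene was called detected at or above 1 TPM in both libraries. Before the data were examined, 25 gene lists and 2 gene families defined by symbol were fixed, with the rule for naming genes, the tests and most alternative settings. Detection of list members was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates, so these tests describe the 2 libraries. Agreement was measured across genes on log2(TPM + 1), a pseudocount of 1.

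Expected counts were rounded to whole numbers for the count methods. The common biological coefficient of variation was estimated with edgeR (intercept only, TMM, default filter on low counts). For genes with a mean count of at least 10, the counts of the libraries were compared by a two-sided exact binomial test on TMM-scaled library sizes, with Benjamini-Hochberg adjustment, an adjusted p under 0.05 and at least a 2-fold difference. Log2 differences were computed with 0.5 added to each scaled count. This test compares these 2 libraries on counting error only. For each list with at least 5 tested members, the median log2 difference was placed among 10000 random lists of the same size, each member being replaced by 1 of 200 genes nearest in mean expression. Poisson counts, which hold counting noise only, were simulated for the 12784 tested genes. On them the binomial comparison at any size recovered 73.0% of genes changed by 1.5-fold, 83.0% at 2-fold and 94.0% at 4-fold. At most 0.0795% of unchanged genes were called. The 2 libraries differed by more than counting noise, so that rate of false calls does not carry over to them. On simulated counts for 12895 genes, a coefficient of variation of 0.10 was recovered as 0.10047. The list shift was tested on 1 list of 14 members per size. For it the observed log2 differences were shuffled over the 12784 genes, and the shift was added to the members. Shifts of 0.5 and 1 lay at percentile 100, a shift of 0.25 at percentile 95.9 with a median of 0.17, and no shift at percentile 2.42 with a median of -0.15. A list shifted by 0.25 therefore stayed within the 1st to 99th percentile in that draw.

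The text names genes by a rule: the 10 highest protein-coding genes outside the mitochondrial genome, the 5 highest genes of other biotypes of at least 300 bases, the top 3 members of each list, fixed sets of globin, erythroid, leukemia and Y-linked genes, detected members of other lineages, the 5 largest differences in each direction at a mean of 5 TPM or more, and 20 genes for isoforms. Genes named outside it are marked as chosen after their values were seen. Hbb-b1, Hbb-b2, Ahsp and Snhg1 had no match by symbol and are not analysed here.

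The alternatives changed the detection threshold, the unit, the pseudocount, the size factors, the filter on counts, the estimate of counts and the dispersion tool (DESeq2), and left out each replicate in turn. Alternatives added after seeing the data were RLE and library-size scaling of the list shifts, TMM on protein-coding genes, uncentred TPM, random lists of protein-coding genes, a correction for GC content and length, 2 further gene lists, DESeq2 on the genes of the edgeR filter, and edgeR's exact test on the genes of the binomial test. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.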

Results

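Total RNA from MEL cells was measured in 2 libraries, replicates 1 and 2 of the same line, at 39453599 and 56660375 expected counts. MEL is a mouse erythroleukemia line that grows as immature erythroid cells. The labels describe the line as the mouse counterpart of human K562 cells. There was a single group, so the measurements below are levels in this line. Their error is the spread between the libraries (SD, n = 2 throughout). For TPM levels this SD also holds the shift of the TPM scale between the libraries, so a small SD can hide a difference. On TMM-scaled counts Gata1 and Ldb1, both with a small SD in TPM, were 1.14-fold and 1.15-fold higher in replicate 2. With 2 libraries of 1 group, no test between conditions was possible.

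Protein-coding genes held 72.2% ± 0.632 of the expected counts but 28.9% ± 3.51 of TPM. The most abundant long noncoding entries were the 7SL RNA genes Rn7s2 (chr12:69361182-69361481, 116500 ± 4008 TPM) and Rn7s1 (chr12:69159295-69159594, 114334 ± 5263 TPM), which are near-identical copies whose split is uncertain. Rn7sk, the RNA that restrains the elongation factor P-TEFb, followed at 78439 ± 7076 TPM. The lincRNA entries Gm42418 (chr17:39846958-39848788) and Gm26917 (chr17:39843013-39846341) together held 8.48% ± 0.324 of the counts. Among protein-coding genes outside the mitochondrial genome, Rplp1 was highest at 4172 ± 262 TPM. It was followed by Lars2 (3302 ± 920 TPM), the translation elongation factor gene Eef1a1 (3268 ± 91.8 TPM) and the histone genes Hist2h2aa2, Hist1h4n and Hist1h4d (3223 ± 644, 2908 ± 466 and 2325 ± 294 TPM). Ppia, Rpl36a, Rpl41 and Rps12 completed the 10 highest, between 1781 and 2212 TPM. Histone and ribosomal protein genes have many close copies, so single-gene levels in these families are uncertain. Genes of biotype rRNA held no counts. Whether reads of ribosomal RNA were counted under Gm42418, Gm26917 or Lars2 was not tested, so the levels of these entries are uncertain too.

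Of 21474 protein-coding genes, 8586 (40.0%) reached 1 TPM in both libraries, 8882 in replicate 1 and 8651 in replicate 2. At 5 TPM the number was 5232. Protein-coding genes held only 31.4% of TPM in replicate 1 and 26.4% in replicate 2. A cut at 1 TPM was therefore stricter than on TPM of protein-coding genes alone, more so in replicate 2. The number was not counted on TPM rescaled to protein-coding genes. The detected genes had a median of 7.81 TPM. No counts were listed in either library for 6525 genes. Across the 7 erythroid lists, 68 of 77 measured members were detected (88.3%), against 5 of 79 members (6.33%) of the 6 lists for other lineages. The second count depended on the threshold and unit. It was 2 at 5 TPM, 11 on FPKM, 15 on TPM rescaled to protein-coding genes, 21 at 0.1 TPM and 24 at 10 expected counts, while the erythroid count ranged from 53 to 76 over these settings. The erythroid lists also include genes that are not restricted to erythroid cells, such as the ubiquitous Alas1. No other cell type was measured, so the contrast between the sets does not by itself show erythroid identity.

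All 12 erythroid transcription factors were detected (Fisher's exact test against other protein-coding genes, adjusted p = 5.4e-05). Gata1, the master regulator of erythroid genes (ENSMUSG00000031162.10, chrX:7959260-7978071), was highest at 100.4 ± 0.601 TPM. Its partners followed, with Ldb1 at 93.4 ± 0.905 TPM, Lmo2 at 77.8 ± 5.72 TPM and Zfpm1, which encodes the cofactor FOG1, at 34.6 ± 1.41 TPM. Klf1, the activator of adult beta globin, stood at 58.2 ± 4.32 TPM, and Tal1 at 7.91 ± 1.81 TPM. Tcf3, Lyl1, Gfi1b and Nfe2 lay between 19.8 and 33.4 TPM. Bcl11a, which represses embryonic globin genes, stood at 14.1 TPM in replicate 1 and 9.93 TPM in replicate 2, and Cbfa2t3 at 4.54 ± 0.792 TPM.

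**Figure D1:**
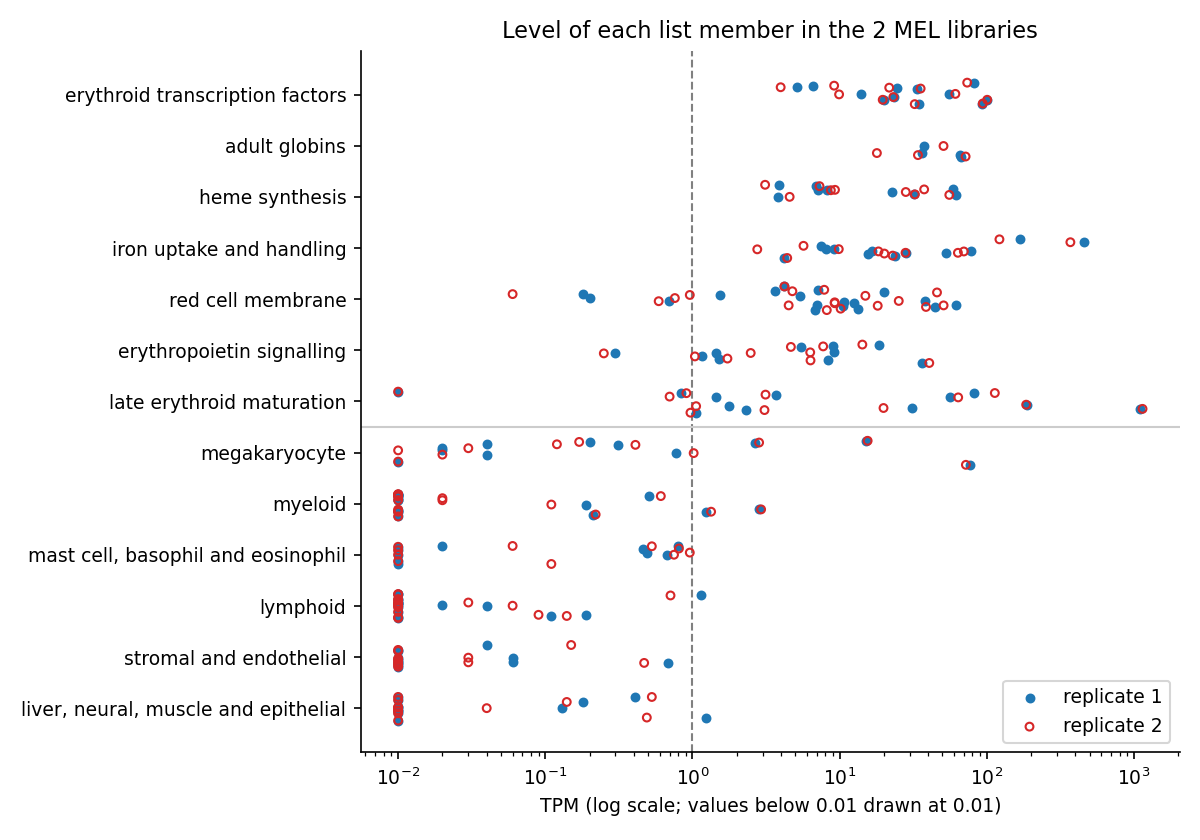
TPM of each member of the 7 erythroid lists (above the grey line) and the 6 other-lineage lists (below it) in replicates 1 (filled) and 2 (open), on a log axis. The dashed line marks 1 TPM, reached in both libraries by 68 of 77 erythroid members and 5 of 79 others (15 on TPM rescaled to protein-coding genes).

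Adult globin transcripts held a small share of protein-coding TPM. Each measured adult globin gene nevertheless stood above the median of detected protein-coding genes (7.81 TPM). No other cell type was measured, so whether these levels are low for erythroid cells was not tested. The 4 measured adult globin genes held 0.0662% ± 0.000047 of protein-coding TPM. The same genes held 0.0250% ± 0.00032 of the expected counts of protein-coding genes and 0.0191% ± 0.0023 of the TPM of all genes. Hba-a1 (chr11:32283511-32284465) stood at 69.6 ± 3.20 TPM, Hbb-bt (chr7:103812524-103813996) at 50.2 ± 22.7 TPM, and Hba-a2 at 44.3 ± 9.36 TPM. Hbb-bs stood at 36.3 TPM in replicate 1 and 17.9 TPM in replicate 2. All 4 were detected (Fisher's exact test, adjusted p = 0.0350). That call was lost at 0.1 TPM (adjusted p = 0.0814), at 10 expected counts (0.0899) and with TPM rescaled to protein-coding genes (0.0597), each with all 4 still detected. The alpha and beta pairs are near-identical copies, so the split within each pair is uncertain. Alpha globin over beta globin was 1.02 in replicate 1 and 2.36 in replicate 2, so this ratio did not hold between the libraries. No embryonic or minor globin was detected (0 of 7). Hbq1b was highest among them at 0.680 ± 0.127 TPM, Hbq1a stood at 0.080 ± 0.0566 TPM and Hbb-y at 0.040 ± 0.0283 TPM. Hba-x had 0 and 2 counts, and Hbb-bh0, Hbb-bh1 and Hbb-bh2 had none. Summed adult globin TPM was 234 ± 6.00 times that of the embryonic and minor genes, which rested on 26 and 42 counts.

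All 9 heme synthesis genes were detected (Fisher's exact test, adjusted p = 6.8e-04). Alad (58.8 ± 4.35 TPM), Cpox (48.1 ± 14.9 TPM), Hmbs (32.2 ± 0.488 TPM) and Urod (25.5 ± 3.78 TPM) were highest. Alas2, the erythroid form of the first enzyme of the pathway, stood at 8.24 ± 1.51 TPM, and its ubiquitous counterpart Alas1 at 3.49 ± 0.523 TPM. Fech, Ppox and Uros lay at 8.44 ± 0.403, 7.12 ± 0.262 and 4.18 ± 0.559 TPM. All 12 iron genes were detected (adjusted p = 5.4e-05, Fisher's exact test), led by the ferritin genes Ftl1 (414 ± 60.8 TPM) and Fth1 (145 ± 32.8 TPM) and the iron-sulfur cluster gene Glrx5 (74.0 ± 5.70 TPM). The transferrin receptor Tfrc stood at 58.2 ± 7.90 TPM.

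Of 18 red cell membrane genes, 14 were detected (Fisher's exact test, adjusted p = 0.00324). Icam4 (56.3 ± 7.62 TPM), Ermap (41.5 ± 3.94 TPM) and Rhd (33.1 ± 18.3 TPM) were highest. Slc4a1, the band 3 anion exchanger of mature red cells, stood at 0.120 ± 0.0849 TPM. In erythropoietin signalling, 9 of 10 genes were detected (Fisher's exact test, adjusted p = 0.00334), a call lost at a threshold of 5 TPM (5 detected, adjusted p = 0.102). The receptor gene Epor stood at 38.5 ± 3.14 TPM, and the signal transducers Stat5a and Stat5b at 16.5 ± 3.10 and 8.38 ± 0.898 TPM. Of 12 late maturation genes, 8 were detected, which did not pass (Fisher's exact test, adjusted p = 0.0998). In replicate 1 alone 10 were detected, and the list passed (Fisher's exact test, adjusted p = 0.00880). It also passed with 11 detected at 0.1 TPM, at 10 expected counts, on FPKM and on rescaled TPM. Carbonic anhydrase 1, Car1, was the highest of the list at 1128 ± 26.1 TPM, followed by Prdx2 (187 ± 1.60 TPM) and Car2 (97.7 ± 22.5 TPM).

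Among 13 progenitor and Friend leukemia regulators, 8 were detected, which did not pass (Fisher's exact test, adjusted p = 0.176). Myb stood at 36.7 ± 3.33 TPM, Myc at 27.2 ± 1.08 TPM and Spi1, which encodes the factor PU.1, at 34.6 ± 0.346 TPM. Fli1 stood at 7.41 ± 0.693 TPM and Gata2 at 1.39 ± 0.431 TPM. The stem cell markers Kit and Cd34 were at 0.175 ± 0.106 and 0.0250 ± 0.00707 TPM. Of 13 p53 pathway genes, 8 were detected, which did not pass (Fisher's exact test, adjusted p = 0.176). In replicate 1 alone 11 were detected, and the list passed (Fisher's exact test, adjusted p = 0.00483). It also passed with 12 detected at 0.1 TPM, at 10 expected counts, on FPKM and on rescaled TPM (Fisher's exact test, adjusted p from 9.2e-04 to 0.00386). Trp53 itself stood at 21.4 ± 2.18 TPM and Bax at 30.4 ± 8.69 TPM. The cell cycle inhibitor genes differed in level, with Cdkn2a at 51.7 ± 12.7 TPM, Cdkn2b at 0.835 ± 0.247 TPM and Cdkn1a, a target of p53, at 0.590 ± 0.0990 TPM. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were detected at 31.5 ± 2.84, 13.8 ± 0.962, 6.83 ± 1.56 and 1.57 ± 0.0990 TPM. All 4 passing gave an adjusted p of 0.0350 in Fisher's exact test, lost at 0.1 TPM, 5 TPM, 10 expected counts and rescaled TPM. Xist, the RNA that coats the inactive X chromosome, had 2 and 1 counts, and Tsix 14 and 13 counts.

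Markers of other lineages were mostly below 1 TPM. None of the 17 lymphoid, 12 stromal and endothelial, 12 liver, neural, muscle and epithelial, and 10 mast cell, basophil and eosinophil genes was detected in both libraries. Adjusted p-values were 6.5e-04, 0.00433, 0.00433 and 0.0126 (Fisher's exact test). At 10 expected counts the last 3 calls were lost (Fisher's exact test, adjusted p = 0.190, 0.420 and 0.774). They were also lost at 5 TPM, where none was detected (Fisher's exact test, adjusted p = 0.0724, 0.0724 and 0.181). The liver and mast cell calls were lost on rescaled TPM (0.101 and 0.794) and at 0.1 TPM, with 3 (0.192) and 4 members detected, and the mast cell call on FPKM (0.251). The lymphoid call held under each of these settings. The myeloid list had 2 of 17 members detected (Fisher's exact test, adjusted p = 0.0350), Prtn3 at 2.88 ± 0.0707 TPM and Cd68 at 1.29 ± 0.0707 TPM. That call was lost at 0.1 TPM and at 10 expected counts, with 5 members each. The megakaryocyte list had 3 of 11 detected, which did not pass (Fisher's exact test, adjusted p = 0.543). Its detected members were the platelet factor gene Pf4 (chr5:90772435-90773383) at 74.5 ± 3.27 TPM, the platelet glycoprotein gene Gp5 (chr16:30307685-30310779) at 15.4 ± 0.205 TPM and Itga2b at 2.75 ± 0.134 TPM.

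Cell cycle and growth genes were abundant. All 15 S phase genes and all 15 G2 and mitosis genes were detected (Fisher's exact test, adjusted p = 6.9e-06 for each). Pcna stood at 118 ± 8.41 TPM, Mcm5 at 82.6 ± 2.81 TPM and Slbp, the histone stem-loop binding protein, at 74.8 ± 8.41 TPM. Top2a, Cdk1 and Birc5 led the mitotic list at 134 ± 23.9, 92.8 ± 16.7 and 69.5 ± 8.79 TPM. All 14 glycolysis genes were detected (Fisher's exact test, adjusted p = 1.4e-05), led by Aldoa (589 ± 298 TPM), Ldha (466 ± 210 TPM) and Pkm (356 ± 256 TPM). Of 87 ribosomal protein genes, 84 were detected (Fisher's exact test, adjusted p = 1.7e-28), and the family held 23.7% ± 1.11 of protein-coding TPM.

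The replication-dependent histones, whose transcripts end in a stem-loop in place of a poly(A) tail, had 57 of 64 members detected (Fisher's exact test, adjusted p = 4.5e-15). Their median was 438 TPM in replicate 1 and 293 TPM in replicate 2, which is 8.63 ± 0.933 times the median of the S phase list. They held 3.60% ± 0.463 of protein-coding counts. All 7 polyadenylated histone variants were detected (Fisher's exact test, adjusted p = 0.00334), with a median of 144 ± 9.98 TPM, led by H2afz (565 ± 134 TPM), H2afx (234 ± 23.8 TPM) and H3f3a (169 ± 21.3 TPM). Among 9 long and structural noncoding RNAs, 7 were detected. Rmrp stood at 26916 ± 433 TPM, Rpph1 at 4199 ± 741 TPM and Malat1 at 46.3 ± 3.94 TPM. The 13 mitochondrial protein-coding genes were all detected (Fisher's exact test, adjusted p = 2.9e-05) and held 0.495% ± 0.0180 of the counts, of which mt-Co1 gave 61.3% ± 3.01. Among 11 interferon-stimulated and 10 heat shock and stress genes, 3 and 5 were detected, neither of which passed (Fisher's exact test, adjusted p = 0.543 for each). Bst2 led the first list at 13.1 ± 0.198 TPM and the chaperone gene Hspa5 the second at 308 ± 29.6 TPM.

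Across the 21474 protein-coding genes, log2(TPM + 1) correlated between the libraries with a Pearson r of 0.996 and a Spearman rho of 0.969. These are correlations across genes, which are not replicates. The common biological coefficient of variation was 0.154 in edgeR over 12471 genes that passed its filter, and 0.160 over 20284 genes without a filter. The square root of the median fitted dispersion in DESeq2 was 0.302 over the 20284 genes and 0.1515 over the 12471. The chi-square between the libraries averaged 56.7 per gene, against 1 for counting noise, with a median of 4.88 against 0.455. The counts therefore differed by more than counting noise alone, which estimated counts of shared reads can also exceed. The TPM scale placed the median detected gene lower in replicate 2 by a log2 difference of -0.22, against -0.01 for TMM-scaled counts. Differences between the libraries are therefore given on TMM-scaled counts.

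**Figure D2:**
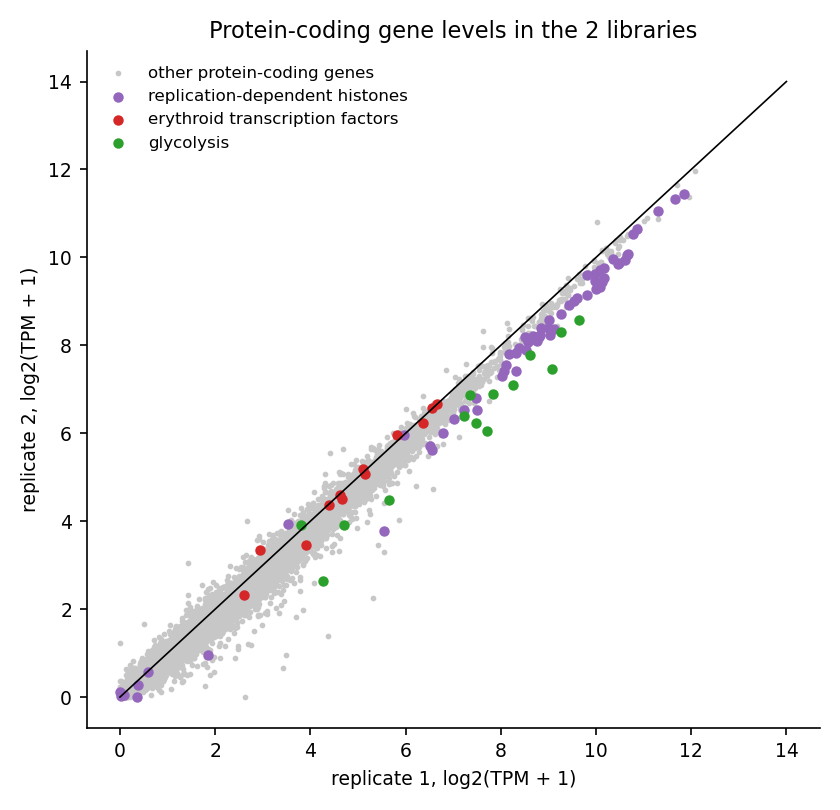
log2(TPM + 1) of each protein-coding gene with counts in replicate 1 (x axis) and replicate 2 (y axis), with 3 lists coloured and the line of equality. Levels correlate (r = 0.996), with the median detected gene below the line by 0.22 on the log2 TPM scale, and 13 of 14 glycolysis genes lie below it.

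Of 12784 tested genes, 398 (3.11%) differed by at least 2-fold, 164 higher in replicate 1 and 234 higher in replicate 2 (exact binomial test on counting error, Benjamini-Hochberg). Under edgeR's exact test on the same 12784 genes, also at 2-fold, the count was 118, 73 higher in replicate 1 and 45 higher in replicate 2. On the 12471 genes of its own filter it was 92, 62 and 30 in the same order. That test set 1 library against 1 library with a dispersion estimated from the same pair, so its spread contains the differences it tests and gives no independent error. In the binomial test at a mean count of 100 or more the count was 149, of which 85 were higher in replicate 1. At any size, 6196 genes (48.5%) passed. Among genes higher in replicate 1 at 5 TPM or more, the largest folds were those of Ddit4 (14.4-fold), an inhibitor of mTORC1 signalling, Trib3 (11.0-fold), Ankrd37 (10.1-fold), the glutathione-degrading enzyme gene Chac1 (9.50-fold) and Anxa2 (4.50-fold). In the other direction, the water channel gene Aqp1 was 3.20-fold higher in replicate 2. Gm8355, Gm24305 and Gm24029, a processed pseudogene and small RNA genes, were 3.68-fold, 2.95-fold and 2.78-fold higher there. The pseudogene Gm10222 had 0.22 and 704 expected counts, a log2 difference of 9.57 that was 1.65 on posterior mean counts. Reads of pseudogenes and of small RNA copies can be shared with other loci, so these last 4 are uncertain.

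Glycolysis genes had the lowest median of any fixed list, at a log2 of replicate 2 over replicate 1 of -0.83, below all 10000 random lists (central 95%, -0.18 to 0.06). Of its 14 members, 13 were higher in replicate 1 and passed at any size, and 5 passed at 2-fold, both over all genes and adjusted over the list alone. Those 5, named after their values were seen except for Pkm (2.68-fold), were Pkm, Slc2a1, Pfkl, Pgam1 and Eno1. The red cell isoform gene Pklr had a log2 difference of 0.07. Replication-dependent histones (-0.41, 57 of 60 members higher in replicate 1), G2 and mitosis genes (-0.26, 15 of 15) and the p53 pathway (-0.24, 10 of 12) also lay below the 1st percentile. At 2-fold, 3 histones, none of the mitotic genes and 1 p53 pathway gene passed, over all genes and adjusted over the list alone. For the p53 pathway the percentile was 4.72 on log2(TPM + 1).

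Above the 99th percentile lay erythroid transcription factors (0.18, 10 of 12 members higher in replicate 2), late maturation genes (0.24, 8 of 11), heme synthesis (0.22, 7 of 9), iron genes (0.15, 8 of 12), interferon-stimulated genes (0.68, 7 of 7) and ribosomal proteins (0.03, 54 of 84). None of the erythroid factor, late maturation or heme genes passed at 2-fold, over all genes or adjusted over the list alone. In the iron and ribosomal lists 1 gene each passed in both ways, against the direction of its list. These were Hmox1 (2.87-fold) and Rpl22l1 (2.77-fold), named after their values were seen and both higher in replicate 1. On TPM without centring the medians of the erythroid factor, late maturation, iron and ribosomal lists turned to values below 0 (-0.0209, -0.0174, -0.0273 and -0.17), and on centred TPM that of the ribosomal list did (-0.0140). Leaving out the centring lowers every list median by the same amount (-0.15) and cannot change a percentile. On centred TPM the percentile of the ribosomal list was above 99. In single draws with the log2 differences shuffled over genes, 14 genes with no shift gave a median of -0.15. In another draw, 14 genes shifted by 0.25 lay at percentile 95.9. For lists of about 14 members, medians of this size are therefore near the limit of the method. The same holds for the mitotic (-0.26) and p53 pathway (-0.24) lists. Each size had a single draw, and the shuffle did not keep genes at their expression level, so the draws set no exact limit. The draws did not cover a list as long as the ribosomal one, with 84 members. In the interferon list 3 genes passed at 2-fold, over all genes and adjusted over the list alone. These were Irf7, Rsad2 and Usp18, named after their values were seen, with fewer than 100 counts in each library. Its percentile was 97.1 to 98.0 on the TPM scales. The other 11 lists with at least 5 tested members lay within the 1st to 99th percentile. They included S phase (0.06), erythropoietin signalling (-0.03), progenitor regulators (0.02), mitochondrial genes (0.09) and red cell membrane genes (0.10). Of the red cell membrane genes, 3 passed at 2-fold, all higher in replicate 2, Rhd and Aqp1 among them.

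**Figure D3:**
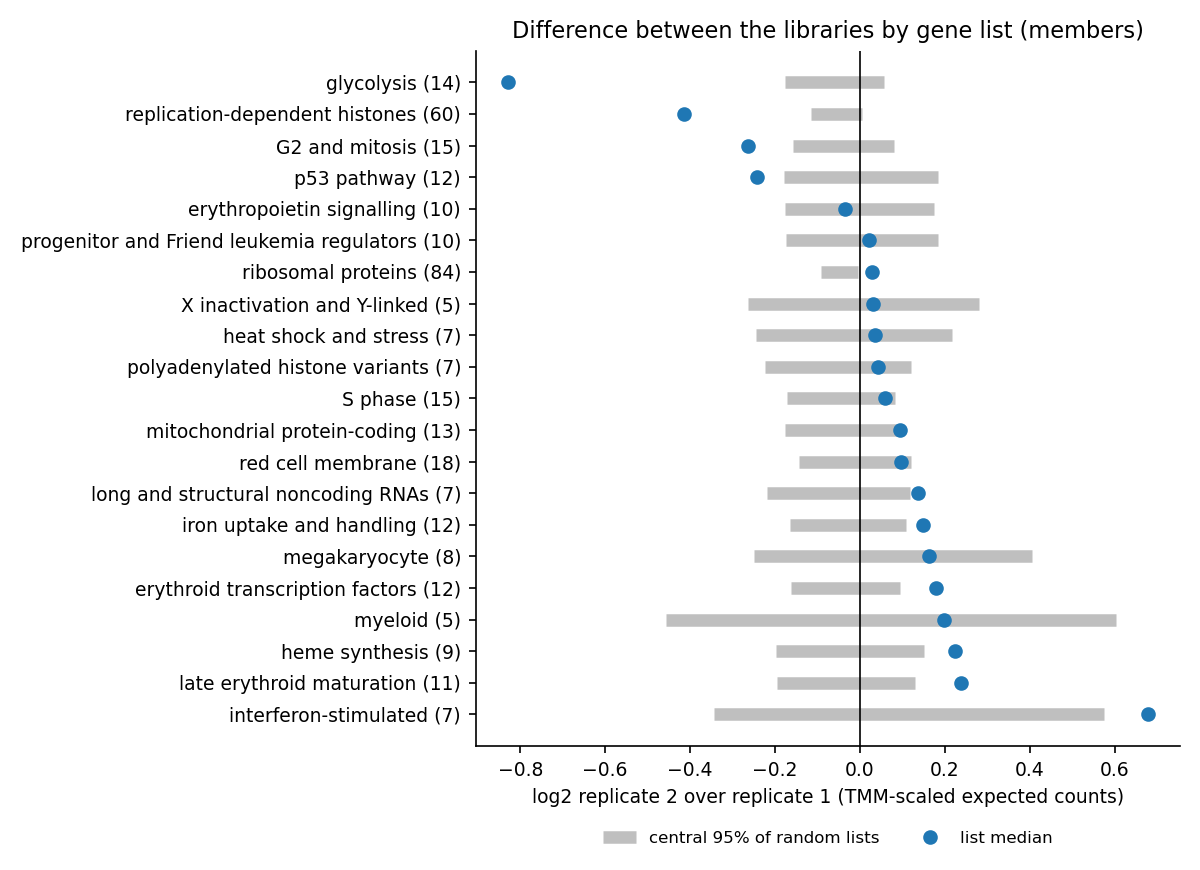
Median log2 of replicate 2 over replicate 1 for each list with at least 5 tested members (points, member number in parentheses) and the central 95% of 10000 random lists matched on expression (grey bars). Glycolysis lies lowest at -0.83, and interferon-stimulated genes highest at 0.68.

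In the transcript tables, the leading transcript was the same in both libraries for 6092 of 6586 genes with at least 2 transcripts and 1 TPM (92.5%). Where the leading transcript held at least 60% in both libraries, it was the same for 3801 of 3807 genes. Of 20 fixed genes, 16 had the same leading transcript. Gata1-201 held 94.4% ± 1.24 of Gata1, Hmbs-201 held 82.9% ± 3.87 of Hmbs, Pkm-201 held 85.2% ± 1.03 of Pkm and Tal1-201 held 85.6% ± 5.45 of Tal1. Lmo2-208 and Nfe2-201 led at 70.5% ± 2.17 and 77.6% ± 4.41. Spi1-201 and Tfrc-201 led their genes at 74.6% ± 7.92 and 63.7% ± 2.28. The leading transcript held a smaller share for Epb41-215 (50.5% ± 3.95), Alas2-201 (43.9% ± 4.14) and Bcl11a-202 (35.8% ± 1.42). Pklr-201 held 68.7% ± 17.7. The leading transcript differed between the libraries for Runx1, Ikzf1, Myb and Kit, of which Kit had only 37 and 44 counts. Slc4a1 rested on 31 and 32 counts. Fech, Epor and Klf1 had a single transcript each, so their agreement, counted among the 16, was fixed in advance.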

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

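The correction for GC content and length, the bound on the scalings, the scalings other than TMM and centred TPM, the test of low-oxygen response genes and the counting limits for the blood cell markers were chosen after the results were seen.

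Signal above a floor of 3 counts appeared in features that enter neither the lists nor the binomial test. The Ensembl genes without a symbol in the annotation used here held 6.84% of the expected counts in replicate 1 and 5.27% in replicate 2. Most of it was in 1 entry, ENSMUSG00000045999.9, with 5.97% and 4.09%. Ensembl genes without a symbol did enter the size factors, the dispersion estimates and edgeR's exact test on its own filter, where they passed that filter. The features with numeric identifiers held 18 counts in replicate 1 and 49 in replicate 2.

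The replication-dependent histones stood above the S phase list in both libraries. Enrichment of the RNA for poly(A) tails would place their median below that of the S phase list. The ratio of the medians was 7.97 in the library where it was lower, and Rmrp, Rpph1 and Rn7sk had mean levels of 26916, 4199 and 78439 TPM, which argues against such enrichment. No biological explanation was tested.

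Markers of other blood cells were detected for megakaryocytes (Pf4 and Gp5 above 10 TPM) and weakly for myeloid cells (Prtn3 at 2.88 TPM and Cd68 at 1.29 TPM). The bound set before the data were examined, most abundant genes of a type below 1 TPM in both libraries with another member of its list above 10 TPM, was met for none of the 3 types: no myeloid or lymphoid member reached 10 TPM, and of the megakaryocyte genes only Ppbp lay below 1 TPM in both libraries. A minority of other blood cells would bring all of their abundant transcripts, and 6 of 7 such genes for myeloid cells and 3 of 3 for lymphoid cells had an upper 95% counting limit below 1 TPM in both libraries, which argues against such cells. For megakaryocytes this held for 1 of 3 genes, Ppbp (at most 0.0864 TPM), while Pf4 was abundant and Gp9 lay at 0.77 and 1.02 TPM, so a minority of megakaryocytes stays open. No biological explanation was tested.

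Glycolysis genes were lower in replicate 2, with a median log2 difference of -0.83. A GC content or gene length bias between the libraries is argued against, since the median was -0.84 after a correction for GC content, length and mean expression that removed 2.40% of the variance over 10935 genes. Among the scalings the median nearest to 0 was -0.78. The scalings of counts moved all list medians by nearly the same amount, at most about 0.05. They could therefore not have brought this median near 0, and that bound decides nothing. For the same reason, the place of the list among random lists hardly depends on the scaling of counts. A stronger low-oxygen response in replicate 1 is 1 possible account. A list of 20 tested low-oxygen response genes outside the fixed glycolysis list lay at percentile 0 of the matched random lists. Its median was -0.42. It still held genes of glucose use, such as Slc2a3 and Pfkfb3, named after their values were seen, so it is not fully separate from glycolysis. Of the 20 genes, 17 were higher in replicate 1, and 3 passed at any size in the other direction. The replication-dependent histones (-0.41) and a list of amino acid response genes (-0.53, described below) also lay at percentile 0. That place is therefore not particular to low-oxygen genes and does not single out this account. The low-oxygen response stays a hypothesis, found and tested on the same 2 libraries, and the labels give no culture difference between them.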

How the results depend on the processing

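The scalings, lists, gene sets and TPM without centring listed as added in the methods were chosen after seeing the data. Leaving out 1 of 2 libraries moves a mean by less than the SD by construction, so those settings test little: detected genes ranged from 8651 to 8882, and isoform agreement and the comparisons between the libraries have no value there. No paired analysis was possible because there is only 1 group. A threshold of 5 TPM gave 5232 detected genes in place of 8586. Detected members of other lineages (5) were 21 at 0.1 TPM, 2 at 5 TPM, 24 at 10 expected counts, 11 on FPKM and 15 on rescaled TPM, while the erythroid lists ranged from 53 to 76. The adult globin share was 0.0250% of expected counts, 0.0658% on posterior mean TPM and 0.0191% of all genes, and the mitochondrial share 0.338% of TPM and 0.542% of posterior mean counts. The correlation was 0.993 with a pseudocount of 0.01 and 0.990 over genes at 1 TPM or more. The coefficient of variation in edgeR was 0.154, with 0.156 by library size and 0.160 without a filter. In DESeq2 it was 0.302 without a filter and 0.1515 on the filtered genes. Without a filter the tools differed on the same genes, so the gene set alone does not account for that gap. The measures are also unlike, a common dispersion in edgeR and a median of fitted dispersions in DESeq2. Genes that differed numbered 1097 at 1.5-fold, 6196 at any size, 149 at a mean count of 100, and under edgeR's exact test with a dispersion from the same 2 libraries 118 on the same genes and 92 on those of its filter, against 398, and 375 of the 398 were shared with library-size scaling. Isoform agreement fell in number, with fewer genes tested, to 3816 at 5 TPM, 2489 at 10 TPM and 3801 at a 60% share. The cause of the other changes was not tested. Between 8 and 10 lists lay outside the 1st to 99th percentile. Among lists outside that range, medians changed sign on log2(TPM + 1) only: ribosomal proteins at -0.0140 centred and -0.17 uncentred, and, uncentred, erythroid transcription factors at -0.0209, iron genes at -0.0273 and late maturation at -0.0174. Leaving out the centring moves all medians by the same -0.15, and library size by about 0.05, and these 2 steps moved percentiles by at most 0.07. The sign changes seen only without centring follow from that constant. The change of the ribosomal list on centred TPM does not. Between TMM-scaled counts and centred log2(TPM + 1) percentiles moved further, as for the p53 pathway from 0.34 to 4.72. Depth limits genes near the floor of 3 counts, such as Cd34 with 5 and 1 counts.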

Other observations

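The lists in this part were chosen after the largest differences had been seen, and they leave out the genes seen there. The genes named below were also chosen after their values were seen.

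Genes of the amino acid response, which the factor ATF4 switches on when amino acids run short, were higher in replicate 1. Of 21 tested members 20 were higher there, and all 20 passed the exact binomial test at any size. The median log2 of replicate 2 over replicate 1 was -0.53, below all 10000 matched random lists (central 95%, -0.17 to 0.07). The cystine transporter gene Slc7a11 was 9.33-fold higher in replicate 1 and Nupr1 5.20-fold, while asparagine synthetase, Asns, was 1.39-fold and Atf4 itself 1.36-fold higher. Wars, a tryptophan tRNA ligase gene, had a log2 difference of 0.02. The comparison covers counting error between 2 libraries only.

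Of the 20 tested low-oxygen response genes outside the glycolysis list, 17 were higher in replicate 1, 14 of which passed at any size. The other 3 were higher in replicate 2, and all of them passed. The 3 that passed at 2-fold were Egln3 (4.40-fold), Ndrg1 (3.16-fold) and Zfp395 (2.14-fold). Pfkfb3, Jmjd6 and Egln1 were the members higher in replicate 2.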
